A study of Mus musculus with 5 samples.

How the data were processed

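The samples were 5 pools of newborn mouse ovary RNA, 3 from Lhx8 null and 2 from wild type animals, each on 1 array. Groups and replicate numbers were taken from the sample labels. A pool held 50 ovaries from at least 25 animals, per the labels' protocols, so replicates were pools. The p-values rest on the spread between pools within groups, drawn by limma's variance model towards that of other genes at a like level. With only 2 wild type pools, the spread within that group is poorly known. Whether pools were dissected or hybridised in shared batches was not given in the sources used here. A wild type replicate 1 was not analysed here.

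The deposited values are array intensities on a linear scale, 1 per probe set and array, and per the labels' protocols they come from biotin-labelled target. The 2% trimmed mean of each array was 500, so the deposited intensities had been scaled per array. Per the submitters' processing notes, GCOS was used for the wild type arrays; the software for the null arrays was not given in the sources used here. No detection calls were used here, and no array was a copy of another (64 to 120 of the 45101 values were equal between any pair of arrays).

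Choices of test, filter, gene lists and alternatives were fixed before the data were examined. Intensities were put on the scale log2(signal + 16). The medians of the arrays differed by 0.38 on that scale, more than the tolerance of 0.1 set for keeping the deposited scaling, so arrays were quantile normalised with limma 3.58.1 in R 4.3.3. Of 45101 probe sets, 64 controls were left out, 34945 had 1 gene symbol, 932 had several and 9160 had none. For 34754 of those with 1 symbol the gene identifier was found in a reference table of assembly GRCm38.p6, which changed 0 symbols. Probe sets with several symbols or none were named nowhere. Each of the 18193 genes was represented by its brightest probe set over all arrays, and the 40% of genes with the lowest mean, below 7.38 or a signal of about 150, were left out (7277 genes), which left 10916. Genome coordinates were not used.

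Differences, null minus wild type, were tested with limma (lmFit, then eBayes with a trend in the variance, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. All adjusted p-values of genes come from that test. The 24 gene lists, drawn from general knowledge of the ovary, its germ cells and neighbouring tissues, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists; 1 list, of Y-linked genes, had no tested member. With an estimated correlation in its place no list passed. For the oviduct list the estimate was -0.0388, below the preset 0.01, so correlation between its members does not account for its lost call. That option also takes the degrees of freedom of its p-values from the few arrays, where the preset correlation takes them from the number of genes. Lists with adjusted p from 1.66e-14 to 2e-04 in camera at the preset correlation then shared 0.153, so that value does not rank them. How much each part adds to the lost calls was not tested. Some genes stand in more than 1 list. List members that matched no probe set with a single symbol were not analysed here. 1 member of the Sertoli list was misspelled when the lists were fixed and found no probe set.

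Genes were named by rule: Lhx8; the 10 largest falls and the 10 largest rises among genes past the threshold whose arrays did not overlap between groups; a fixed set of oocyte, germ cell and granulosa genes (Nobox, Figla, Sohlh1, Sohlh2, Gdf9, Bmp15, Zp1, Zp2, Zp3, Kit, Kitl, Pou5f1, Ddx4, Dazl and Foxl2); and up to 4 members of each list with the smallest p. Other list members are named mostly where few went one way or failed to pass, and these were chosen after their values were seen.

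The steps were tested on simulated arrays of the same size, 3 against 2, over 10916 genes. The share of changed genes called in the right direction was 6.38% at a log2 change of 0.5, 58.7% at 1, 91.1% at 2 and 94.9% at 4, and 6.09% of calls were false. Of 20 unchanged lists 0 were called, and of 5 changed lists 5. The simulated noise was independent between genes, so lists with correlated members were not tried. Only 39 to 47 genes changed at each size, while 47.8% of tested genes passed in the data, so these shares need not hold there. Small changes can still be missed with these arrays.

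Alternatives covered the scaling between arrays, the added constant (1 or 64), the brightness filter, the choice of probe set, the variance model, the threshold, the replicate number as a block, each array left out in turn, camera with an estimated correlation and limma's fry. The counts of list members without null replicate 1 were added after the data were seen, since that array had the lowest correlations within its group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.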

Results

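RNA from newborn mouse ovaries was measured on 5 oligonucleotide arrays, 3 from Lhx8 null animals (replicates 1, 2 and 3) and 2 from wild type animals (replicates 2 and 3). Each array carried the biotin-labelled target of 1 pool of 50 ovaries taken at postnatal day 0.5, on a mixed C57/129 background. Lhx8 encodes a LIM homeodomain transcription factor of oocytes, and the comparison asked which transcripts differ in newborn ovaries that lack it. The deposited intensities had a trimmed mean of 500 on every array. Their median on the log2(signal + 16) scale was 7.18, 7.00 and 7.00 on the null arrays and 6.80 and 6.83 on the wild type arrays. After quantile normalization the correlation across probe sets was 0.960 to 0.974 between null arrays, 0.970 between the wild type arrays and 0.905 to 0.931 between arrays of different groups. The number of arrays, 3 against 2, limits the precision of all values.

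Lhx8 itself had signals of 332.6, 159 and 347.4 in null replicates 1, 2 and 3, against 6450.1 and 5223.1 in wild type replicates 2 and 3. The means were 280 ± 105 (SD, n = 3) and 5837 ± 868 (SD, n = 2), and the normalised level fell by 4.45 on the log2 scale (SE 0.29, adjusted p = 1.08e-05). Lhx8 had 1 probe set, and its place relative to the deleted part of the gene was not given in the sources used here.

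The deepest falls in Lhx8 null ovaries included members of the maternal effect and zona pellucida gene lists. Nlrp4f, an oocyte-expressed member of the NLRP family, fell by 8.23 on the log2 scale (SE 0.29, adjusted p = 8.18e-07, 3 null against 2 wild type arrays), from a mean signal of 7237 ± 1558 (SD, n = 2) to 11.3 ± 10.4 (SD, n = 3). Its relatives Nlrp14 and Nlrp5 had log2 fold changes of -7.12 (SE 0.45) and -5.72 (SE 0.35), and Padi6, an oocyte peptidylarginine deiminase, fell by 6.64 (SE 0.33). The zona pellucida glycoprotein genes Zp2 and Zp3 fell, at -6.51 (SE 0.58) and -6.30 (SE 0.32). Btg4, which acts in the decay of maternal mRNA, fell by 5.55 and Tcl1, a coactivator of Akt kinases, fell by 5.32. Iqca and 4930562C15Rik were among the largest falls too, at -5.46 and -5.38. A second, dimmer probe set of Iqca, with signals of at most 96.8 on any array, had a log2 fold change of 0.03 and did not follow. The folds are on the log2(signal + 16) scale, and those of genes close to background in null ovaries depend on the added constant: Nlrp4f fell by 6.69 with 64 in place of 16.

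The largest rises included Wfdc2 and Ovgp1 of the oviduct gene list and several homeobox and other transcription factor genes. Wfdc2, which encodes a secreted epithelial protein, rose by 5.24 on the log2 scale (SE 0.14, adjusted p = 2.56e-07), from a mean signal of 128 ± 20.3 (SD, n = 2) to 6010 ± 418 (SD, n = 3). The transcription factor genes Hand2, Osr2, Hoxa10 and Hoxa11 rose by 4.88 (SE 0.22), 4.23 (SE 0.19), 3.89 (SE 0.23) and 3.77 (SE 0.24). Ovgp1, the oviductal glycoprotein gene, rose by 4.30 (SE 0.22) and Plet1 by 4.37 (SE 0.15). The urea transporter gene Slc14a1 rose by 4.08, Rsph3a, a radial spoke gene, by 3.96 and Moxd1 by 3.71. Of these 10 genes all but Rsph3a and Moxd1 had a mean wild type signal below the brightness cutoff, so their folds depend on the added constant. With 64 in place of 16, Wfdc2 rose by 4.87, Hand2 by 4.17, Plet1 by 3.91, Osr2 by 3.80, Ovgp1 by 3.79, Slc14a1 by 3.46, Hoxa10 by 3.26 and Hoxa11 by 3.09. Dimmer probe sets of Hand2, Hoxa10, Osr2, Plet1 and Rsph3a gave smaller values, such as 0.87 for Hoxa10 and 0.27 for Osr2. Those of Hoxa10 and Osr2 had signals of at most 66.9 and 42.4 on any array, below the brightness cutoff, so they say little. Other probe sets of Plet1, Slc14a1 and Hand2 rose by 4.14, 3.02 and 2.35.

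**Figure D1:**
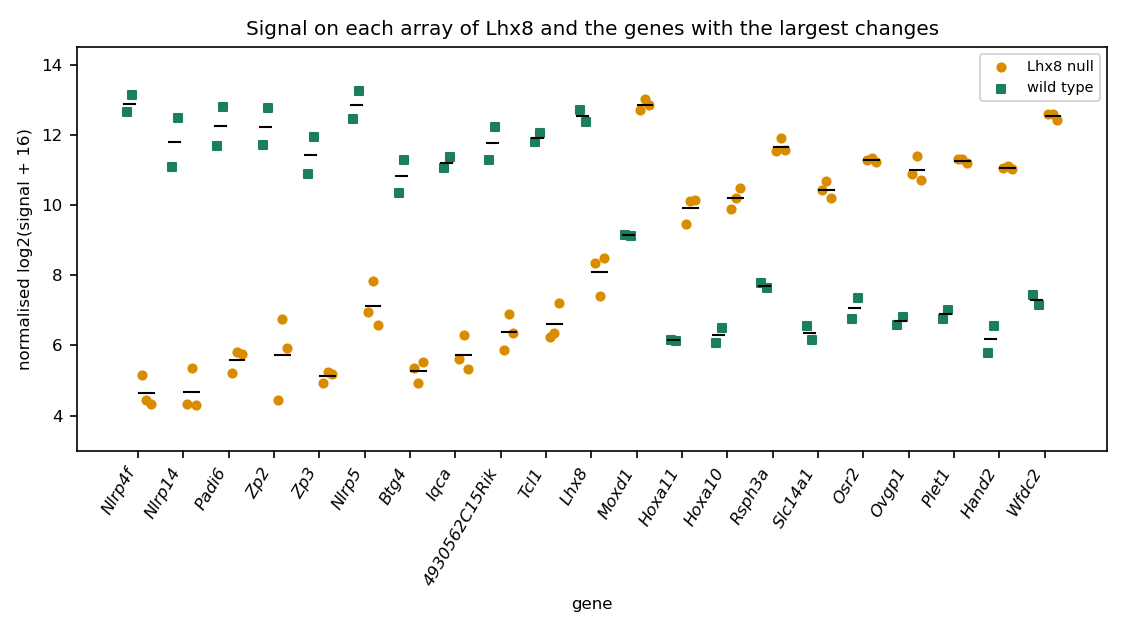
Normalised log2(signal + 16) of Lhx8 and of the 10 genes with the largest fall and the 10 with the largest rise, with 1 point per array (circles, Lhx8 null, n = 3; squares, wild type, n = 2) and a line at each group mean. No null array overlaps a wild type array in any of these genes, and Nlrp4f fell by 8.23 while Wfdc2 rose by 5.24.

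Across the genome, 2791 genes were higher and 2429 lower in Lhx8 null ovaries, and 5696 of the 10916 genes tested did not pass (limma, two-sided, Benjamini-Hochberg adjusted p below 0.05). At 2-fold or more, 969 were higher and 887 lower, and at 16-fold or more 6 were higher and 31 lower. The null and wild type arrays did not overlap for 67.8% of the tested genes, where chance gives 20%. Higher genes made up 53.5% of the calls, and 33.5% with each array centred on its median (1720 higher, 3422 lower), a scaling that moved the median log2 fold change of the tested genes from 0.04 to -0.18. The share was 50.9% without the brightness filter (2871 higher, 2774 lower) and 48.7% with each gene's probe sets averaged. Without wild type replicate 3, 1846 genes were higher and 1543 lower. The bacterial and phage hybridisation controls also differed by group: BioC was 2.18 times and Cre 1.86 times as bright on null as on wild type arrays, and the 18S ribosomal RNA probe sets 1.96 times, with every null array above every wild type array. The ratio of the 3' to the 5' probe set of Actb, a measure of RNA integrity, was 1.69, 1.60 and 1.48 on null arrays and 1.43 and 1.39 on wild type arrays. That of Gapdh overlapped between the groups, at 0.802, 0.658 and 0.660 on null arrays and 0.666 and 0.625 on wild type arrays. Array batches were not given in the sources used here.

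**Figure D2:**
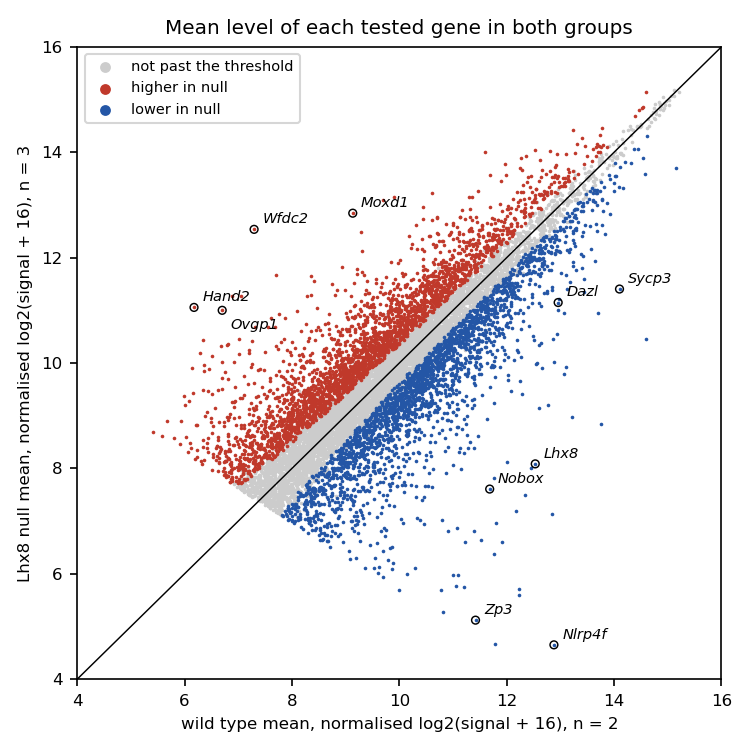
Mean normalised log2(signal + 16) of each of the 10916 tested genes in wild type (x axis, n = 2) and Lhx8 null ovaries (y axis, n = 3), coloured by whether the gene was higher (2791), lower (2429) or not past the threshold, with the line of equality. Oocyte genes such as Nlrp4f, Zp3, Nobox and Lhx8 lie far below the line and Wfdc2, Hand2 and Ovgp1 far above it.

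Genes of the oocyte transcription factor list mostly fell. Of the 8 tested, 7 fell and none rose, with a median log2 fold change of -2.15 (two-sided camera test, adjusted p = 9.96e-06). The 7 include Lhx8 itself, at -4.45, whose loss defines the groups, and the set was not tested without it. The call was lost at adjusted p = 0.153 with an estimated correlation. The regulators of early oocyte development Nobox, Figla, Sohlh2 and Sohlh1 fell, with log2 fold changes of -4.08 (SE 0.27), -3.17 (SE 0.24), -2.35 (SE 0.25) and -1.96 (SE 0.20). Foxo3, named as the exception after its value was seen, had -0.38. Adjusted over the list alone, 7 fell. Gata4, named after its value was seen, was among these, at -1.31. Whether each member is restricted to oocytes was not tested. Pou5f1 was too dim on average to be tested. In the fit without a brightness filter it fell by 3.42 (adjusted p = 0.000282).

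The egg coat genes tested fell, and the list that joins them with secreted oocyte factors moved both ways. Zp1, Zp2, Zp3 and the growth factor gene Gdf9 fell, at -4.32, -6.51, -6.30 and -4.62. Ovgp1, an oviduct product that binds the zona and stands in the oviduct list too, and Bmp6 rose by 4.30 and 0.79. The list was tested only with Ovgp1 in it. With 4 of 6 lower and 2 higher, and the same counts adjusted over the list alone, the list as a set did not pass (median -4.47, adjusted p = 0.0988, and adjusted p = 0.469 with an estimated correlation). Of its 6 members left out as dim, 4 fell and 0 rose in the fit without the brightness filter. Among them was Bmp15, at -2.02 (adjusted p = 0.0123), whose other probe sets gave -2.46 and 0.44.

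Of the maternal effect and oocyte-expressed genes, 16 of 18 fell and 1 rose, with a median of -3.21 (adjusted p = 1.1e-09), and adjusted over the list alone the counts were equal. The call was lost at adjusted p = 0.153 with an estimated correlation. Besides the NLRP genes and Padi6, Dppa3, a maternal factor that protects DNA methylation in the zygote, fell by 4.13 (SE 0.19), and Cpeb1, a regulator of stored mRNA, fell by 3.95 (SE 0.19). The exceptions, picked out after their values were seen, were Plat, which rose by 0.37, and Ube2d2a, at -0.15. The brightness filter acted on the mean over all arrays and so removed genes that fell to background: of the 23 dim members 14 fell without it, which brought the list to 30 fallen and 1 risen.

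Genes that mark germ cell identity fell as a group, with 27 of 29 lower, none higher and a median of -2.18 (adjusted p = 1.66e-14). All 29 fell when adjusted over the list alone. With an estimated correlation the call was lost (adjusted p = 0.153 with an estimated correlation). Gtsf1, Tdrd5 and Piwil2, which act in the piRNA pathway, fell, at -4.91 (SE 0.13), -3.16 (SE 0.16) and -2.90 (SE 0.19), and the RNA-binding protein gene Elavl2 fell by 4.24 (SE 0.18). Ddx4 and Dazl, general markers of germ cells, fell too, at -2.70 (SE 0.20) and -1.81 (SE 0.20). Dazl fell by 2.46 at its other probe set. In wild type ovaries Dazl had a mean signal of 7709 ± 998 (SD, n = 2), and in null ovaries 2261 ± 556 (SD, n = 3).

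Of the meiotic prophase genes, 18 of 20 fell and none rose (median -1.74, adjusted p = 5.58e-08), with the same counts adjusted over the list alone. This call was also lost, at adjusted p = 0.153 with an estimated correlation. Syce1 and Sycp3, components of the synaptonemal complex, had log2 fold changes of -2.82 (SE 0.17) and -2.70 (SE 0.17), and Tex12 and Syce2 fell too, at -2.26 and -1.46. Trip13 and Rec8, singled out because they did not pass, had 0.17 and 0.47. Of 11 dim members 4 fell and 1, Stra8, rose in the fit without the filter.

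Pluripotency genes moved both ways. Tcl1, Dppa3, Dppa5a, Dppa4 and Lin28a fell, at -5.32, -4.13, -3.90, -2.02 and -1.18. Prdm1, a repressor also needed for germ cell specification, rose by 1.74, Klf4 by 1.09 and Tfcp2l1 by 0.56. With 5 of 8 lower and 3 higher, also adjusted over the list alone, the set did not pass (median -1.60, adjusted p = 0.0988, and adjusted p = 0.464 with an estimated correlation), although it did without null replicate 3 (adjusted p = 0.0474). Of its 10 members left out as dim, 4 fell and 0 rose in the fit without the brightness filter.

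Granulosa and pregranulosa genes, expressed by the somatic cells around the oocyte, mostly fell. Of 22 tested, 14 fell and 2 rose (median -0.79, adjusted p = 2e-04), with the same counts adjusted over the list alone. The call was lost at adjusted p = 0.153 with an estimated correlation. Runx1 and the inhibin subunit gene Inhbb fell, at -2.18 (SE 0.24) and -1.71 (SE 0.18), as did Foxl2, a transcription factor of granulosa cells, at -1.35 (SE 0.17), and Irx3 at -1.17 (SE 0.14). Kitl, the ligand of KIT, fell by 0.59 (SE 0.09), with -1.20 and -1.48 at 2 of its other probe sets. The members that rose, named after their values were seen, were Lgr5 (0.93) and Bmp2 (1.08).

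Of 5 steroidogenic genes, Hsd3b1, Nr5a1 and Star fell, at -1.16, -1.33 and -0.90, and Fdx1 rose by 0.48, a call lost without wild type replicate 2 (adjusted p = 0.069) or 3 (adjusted p = 0.104) and after median centring, where Fdx1 stood at 0.16 (adjusted p = 0.364). Adjusted over the list alone 3 fell and 2 rose. Of 7 Sertoli and testis genes, Vnn1, Aard, Ptch1 and Clu fell, at -1.52, -1.24, -0.78 and -0.47, and Fgf9 and Ptgds rose, by 1.80 and 0.93, also when adjusted over the list alone. Neither set passed, with adjusted p = 0.34 for the steroidogenic and adjusted p = 0.326 for the Sertoli list, and adjusted p = 0.469 with an estimated correlation for both.

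**Figure D3:**
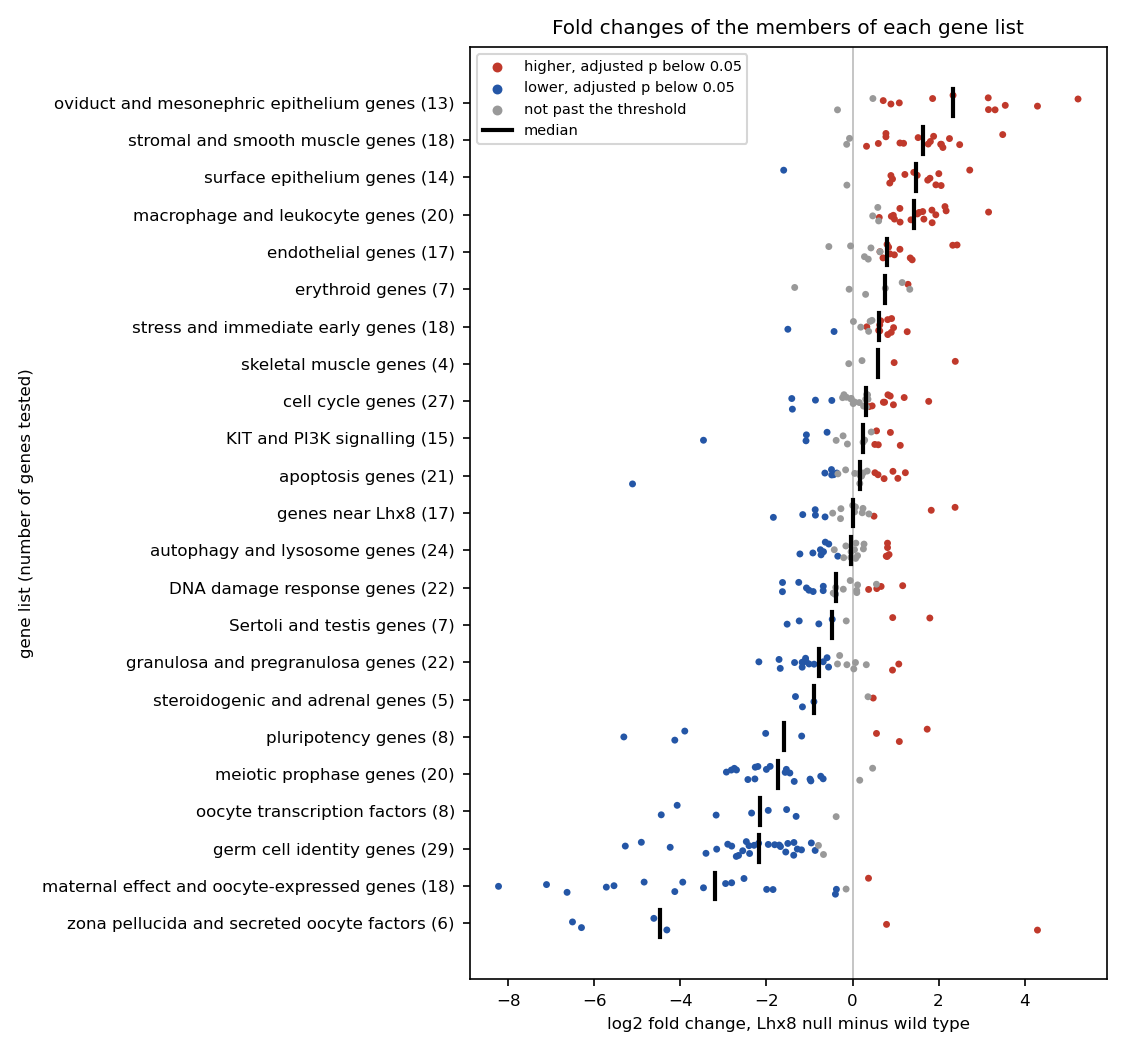
Log2 fold change (x axis, Lhx8 null minus wild type) of each tested member of 23 gene lists (y axis, with the number of genes tested), coloured by whether it was higher, lower or not past the adjusted p threshold, with a bar at the list's median. Medians run from -4.47 in the zona pellucida list to 2.34 in the oviduct list.

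Genes of the oviduct and mesonephric epithelium had the highest median of the 23 lists tested. Of 13 tested, 11 rose and none fell (median 2.34, adjusted p = 3.26e-06), and 12 rose when adjusted over the list alone. The call was lost at adjusted p = 0.153 with an estimated correlation. Besides Wfdc2 and Ovgp1, the tight junction gene Cldn3 rose by 3.55 (SE 0.21) and Wnt7a, a signal of the tract epithelium, by 3.16 (SE 0.24). Emx2 and Elf3, listed because they did not pass, had -0.35 and 0.47. Surface epithelium genes rose in 12 of 14 cases (median 1.47, adjusted p = 4.33e-05), with equal counts adjusted over the list alone, and their call too was lost at adjusted p = 0.153 with an estimated correlation. The mesothelial gene Msln rose by 2.73 (SE 0.17), Upk1b by 1.94 (SE 0.13) and Upk3b by 1.75 (SE 0.13), while the retinaldehyde dehydrogenase gene Aldh1a1 fell by 1.60 (SE 0.11). Like every list that rose or fell, both were compared between arrays whose controls differed by group, with BioC 2.18 times as bright on null arrays.

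Stromal and smooth muscle genes rose in 16 of 18 cases and fell in none (median 1.64, adjusted p = 1.5e-07), also when adjusted over the list alone. The call was lost at adjusted p = 0.153 with an estimated correlation. Thy1 rose by 3.49 (SE 0.19), the smooth muscle gene Tagln by 2.05 (SE 0.12) and the matrix gene Postn by 1.81 (SE 0.10). Macrophage and leukocyte genes rose in 17 of 20 cases, and in 18 adjusted over the list alone, with none lower (median 1.43, adjusted p = 1.05e-07, lost at adjusted p = 0.153 with an estimated correlation). The galectin gene Lgals3 rose by 3.16 (SE 0.21), the receptor gene Csf1r by 1.94 (SE 0.13) and the complement gene C1qb by 1.85 (SE 0.16). Of 17 endothelial genes 11 rose and none fell, with the same counts adjusted over the list alone (median 0.80, adjusted p = 0.000381, lost at adjusted p = 0.361 with an estimated correlation). Sox17 rose by 2.43, Plvap by 2.33 and Kdr, a VEGF receptor gene, by 1.10.

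Markers of blood and skeletal muscle did not pass as sets. Of 7 erythroid genes Alas2 rose (1.29, SE 0.32), a call lost without wild type replicate 2 (adjusted p = 0.0767) or 3 (adjusted p = 0.0683), and the other 6 did not pass. Of these, Car2 (1.69, adjusted p = 0.000368) and Slc4a1 (1.99, adjusted p = 0.00296) passed without null replicate 3, and Rhd (-2.04, adjusted p = 0.0186) passed without null replicate 2. The set had adjusted p = 0.496, adjusted p = 0.785 with an estimated correlation and adjusted p = 0.0474 without null replicate 3. Of 4 skeletal muscle genes Acta1 and Casq1 rose by 2.39 and 0.97, and the set had adjusted p = 0.438 and adjusted p = 0.672 with an estimated correlation. Without wild type replicate 3 neither passed (adjusted p = 0.12 and 0.141), and without wild type replicate 2 Acta1 did not (adjusted p = 0.0606). Adjusted over the list alone the counts of both lists were unchanged. All 6 Y-linked genes measured were too dim to be tested and none passed without the filter.

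Signalling and cell death genes moved both ways. In the KIT and PI3K list Kit, the receptor through which KIT ligand acts on the oocyte, fell by 3.46 (SE 0.20), and Cdkn1b, Pdpk1 and Kitl fell, at -1.08, -1.07 and -0.59. Akt1 rose by 1.11 (SE 0.17), as did Rps6 (0.88), Tsc2 (0.60), Akt2 (0.56) and Pik3ca (0.52), the last 4 named after their values were seen. Pdpk1 stood at 0.22 when the gene's probe sets were averaged. The list had 5 higher and 4 lower of 15, and 7 higher adjusted over the list alone. Its median of 0.25, mean of -0.15 and downward test differed in sign (adjusted p = 0.897, and adjusted p = 0.899 with an estimated correlation), and the median was -0.05 with arrays centred on their medians. Of 21 apoptosis genes 6 rose and 6 fell, also when adjusted over the list alone. Trp63, whose protein guards the genome of oocytes, fell by 5.12 (SE 0.48), while Tnfrsf1a and Apaf1 rose by 1.06 and 0.94. That list's median was 0.17 and its mean -0.08, with a median of -0.10 after median centring (adjusted p = 0.784, and adjusted p = 0.785 with an estimated correlation).

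Of 24 autophagy and lysosome genes 8 fell and 5 rose, also adjusted over the list alone (median -0.04, adjusted p = 0.496, and adjusted p = 0.588 with an estimated correlation), and the median was -0.32 after median centring. Atg12 and Atg5, which act in the same conjugation system, fell, at -1.22 and -0.92, and the protease gene Ctsb and Gabarap rose by 0.85 and 0.78. DNA damage response genes fell in 9 of 22 cases and rose in 4, or 5 adjusted over the list alone (median -0.39, adjusted p = 0.0473, lost at adjusted p = 0.207 with an estimated correlation), and the median was -0.64 after median centring. Rad50, part of the complex that binds broken DNA ends, fell by 1.63 (SE 0.14) and Gadd45a fell by 1.63 (SE 0.20). That call was lost without null replicate 2 (adjusted p = 0.0613), null replicate 3 (0.0705) or wild type replicate 3 (0.0523).

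Cell cycle genes rose in 9 of 27 cases and fell in 4, also adjusted over the list alone (median 0.31, adjusted p = 0.186, and adjusted p = 0.672 with an estimated correlation), and the median was 0.03 after median centring. The proliferation markers Mki67 and Top2a rose by 1.77 (SE 0.13) and 1.20 (SE 0.12), and the mitotic genes Ube2c and Bub1 fell, at -1.41 (SE 0.12) and -1.40 (SE 0.14). Stress and immediate early genes rose in 11 of 18 cases and fell in 2, with equal counts adjusted over the list alone (median 0.62, adjusted p = 0.0317, lost at adjusted p = 0.336 with an estimated correlation), and the median was 0.38 after median centring. Jun, Hspa1b and Ddit3 rose by 0.96, 1.27 and 0.82 and the heat shock gene Hsph1 fell by 1.50. The stress call was lost without wild type replicate 2 (adjusted p = 0.147).

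Genes that neighbour Lhx8 on its chromosome moved both ways. Of 17 tested, 5 fell and 3 rose, also adjusted over the list alone, with a median of 0.00 (adjusted p = 0.513, and adjusted p = 0.78 with an estimated correlation) and of -0.24 after median centring. Nexn fell by 1.84 (SE 0.20), and Negr1 and Ak5 rose by 2.39 (SE 0.22) and 1.83 (SE 0.21).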

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

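No test of the control signals was planned, and their comparison was added after the data were seen. Signals of 5 control transcripts, which no gene comparison used, were higher on every null array than on every wild type array; the differences are null minus wild type, in log2 of the deposited signal, over 3 and 2 arrays. The BioB hybridisation control differed by 0.8246, or 1.77 times. The BioC hybridisation control differed by 1.124, or 2.18 times. The BioD hybridisation control differed by 0.6355, or 1.55 times. The Cre hybridisation control differed by 0.8921, or 1.86 times. The 18S ribosomal RNA probe sets differed by 0.9704, or 1.96 times.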

How the results depend on the processing

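Alternatives were planned, except the list counts without null replicate 1, chosen after the data were seen; these stayed within 1.5 times, save for skeletal muscle, with 1 member in place of 2. Lhx8 stayed lower and past the threshold throughout, from -4.65 to -4.11 over the fits that left out 1 array. Median centring gave 1720 higher genes; testing all probe sets singly gave 5215 higher and 4949 lower, with more features tested; requiring 2-fold gave 969 and 887. Leaving out 1 array gave 1846 to 2916 higher and 1543 to 2622 lower, the fewest without wild type replicate 3. With replicate number as a block, over replicates 2 and 3, 2997 genes were higher and 2668 lower and Lhx8 was at -4.62. Of the named genes Car2 (1.03), Slc4a1 (1.37) and Rhd (-1.57) then passed (adjusted p 0.01, 0.0112 and 0.00814). That fit, over 2 arrays of each group, left few residual degrees of freedom, so its p-values rest mostly on limma's variance model. Its calls are therefore no firmer than those over all arrays. On the log2 scale Car2 and Slc4a1 were lower in null replicate 3 (9.86 and 8.16) than in wild type replicate 3 (10.02 and 8.45). Rhd was higher in null replicate 2 (8.85) than in wild type replicate 2 (8.66). The replicate numbers are shared by 2 arrays of each group and no label ties them to a litter or day. Deviations from the group means correlated at -0.134 for number 2 and 0.101 for number 3. The deviations of the 2 wild type arrays are mirror images of each other, so these values cannot show whether the numbers pair arrays. Null replicate 1, which has no partner, gave 0.178 with wild type replicate 2 and -0.178 with 3.

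With an estimated correlation the adjusted p was 0.153 for the oocyte transcription factor, maternal effect, germ cell, meiotic, granulosa, macrophage, stromal, surface epithelium and oviduct lists, 0.207 for DNA damage, 0.361 for endothelial and 0.336 for stress genes. The zona list passed without the brightness filter (0.00402), with all probe sets (0.0107), with the replicate block (0.0201) and by fry (0.0193). The pluripotency list passed in the same order at 0.0116, 0.00598, 0.0213 and 0.00609 and with probe sets averaged (0.00241). By fry, which does not compare a list with other genes, the steroidogenic (0.00609) and Sertoli (0.00809) lists passed. Cell cycle genes passed with all probe sets (0.0126). DNA damage genes did not pass with probe sets averaged (0.105) or with the block (0.0505), nor stress genes with 60% left out (0.19). Leaving out 1 array, adjusted p ranged from 0.0474 to 0.287 for pluripotency, 0.0318 to 0.0705 for DNA damage, 0.0474 to 0.829 for erythroid and 0.0113 to 0.147 for stress genes. Pdpk1 turned from -1.07 to 0.22 with probe sets averaged. Except where a reason is given, the cause was not tested.

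Of 107 named genes, 106 kept direction and side of the threshold under median centring and 107 as deposited. With probe sets averaged 96 did, and Bmf, Atr, Xrcc6, Des and Pigk no longer passed (limma, adjusted p 0.389, 0.0879, 0.663, 0.0592 and 0.298). Most named genes were picked for large changes or small p, so they were likely to keep their side. Over all calls, median centring kept 1715 of 2791 higher and 2413 of 2429 lower genes, and averaging kept 1896 and 1846. Some settings hold fewer named genes, since the probe choice and filter were redone: without 1 wild type array, fallen oocyte genes drop below the filter. Signal over background limits the folds of genes near background in either group.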

Other observations

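Gene families were grouped by a shared name stem of at least 10 tested genes. At the preset correlation a few passed as sets in Lhx8 null ovaries, 8 of 117 with the members that stand in the fixed lists and 5 of 108 without. The screen without list members and the values of Stra8 and Dmrt1 were chosen only after results were seen. So were the comparisons of oviduct with granulosa genes and of maternal with meiotic or germ cell genes. With list members left out, 22 of 27 collagen genes (Col) rose and none fell, with a median log2 fold change of 1.03 (camera, adjusted p = 2.05e-05). Of 14 small nucleolar RNA host genes (Snhg) 10 rose (0.74, adjusted p = 0.0283), and of 11 Adamts protease genes 6 rose (0.75, adjusted p = 0.04). In the other direction, 20 of 40 ubiquitin-specific protease genes (Usp) fell and 6 rose (-0.39, adjusted p = 0.0258), and 18 of 47 mitochondrial ribosomal protein genes (Mrpl) fell and 1 rose (-0.30, adjusted p = 0.0283). These were the 5 of 108 families of genes outside the fixed lists past the threshold; none of the 5 medians changed sign under the other scalings, though median centring moved Usp to -0.67 and Mrpl to -0.59, and 0 passed with an estimated correlation (adjusted p = 0.72). With list members included, 8 of 117 families passed: the same 5, Tex and Cldn, which kept fewer than 10 genes without list members, and Taf, which no longer passed without them (adjusted p = 0.0758). With list members included, 0 of the 117 passed with an estimated correlation (adjusted p = 0.701).

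Stra8, a gene of meiotic entry, and Dmrt1, a transcription factor gene of the gonads, rose in null ovaries. Both were too dim on average to be tested with the filter. Stra8 had signals of 293.7, 374.6 and 285.4 on null arrays against 11 and 65.6 on wild type arrays, a rise of 2.64 on the log2 scale (adjusted p = 0.00303 without the filter, limma), and 1.82 to 3.42 when 1 array was left out. Dmrt1 had 264.3, 293.7 and 387.8 against 47.1 and 24.6, a rise of 2.50 (adjusted p = 0.00086), and 2.16 to 2.81 when 1 array was left out.

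Genes of the oviduct and genital tract rose in null ovaries, while granulosa genes mostly fell. A smaller share of germ cells alone would raise all other cell types alike. On these arrays the oviduct list lay 3.125 above the granulosa list in median log2 fold change (95% bootstrap interval over genes 1.47 to 4.33). These lists were paired after their medians were known, and the interval leaves out the spread between pools. The difference thus describes the lists and does not test that share. A scaling difference that depends on brightness is argued against by the oviduct median, at percentile 100 of 10000 random lists matched on mean level. The central 95% of those lists ended at 0.54. More tract tissue in the null pools is a candidate explanation: of 28 tract marker genes outside the 40 largest rises, 20 rose and 2, Esrp1 and Marveld2, fell, with a median of 1.544. Over all 34 markers, posterior Hox genes rose in 7 of 7 cases, mesenchyme genes in 9 of 10 and simple epithelium genes in 10 of 17; the marker groups were written after the largest rises had been seen, and ovarian surface epithelium and stroma express some of these genes. A change in the ovary's own cells stays open.

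Oocyte genes fell further than meiotic genes. A smaller share of germ cells as the whole cause would lower both alike if only germ cells expressed their members. The medians differed by -1.468 (permutation test of list membership, two-sided p = 0.00113, adjusted p = 0.00252, 18 and 20 genes). Permuting genes does not cover the spread between pools. Among genes with a wild type level of at least 10 on the log2 scale, the difference was -1.274 (permutation p = 0.0898, 16 and 9 genes), so a background limit on dim meiotic genes could not be excluded there. A wider comparison added after that result, of 16 maternal genes with 29 germ cell and meiotic genes at that level, gave -1.3 (permutation p = 0.00168, adjusted p = 0.00252). In all, 3 such tests were run. Some of the 29 kept a high level in null ovaries, such as Trip13 (10.7 in null, 10.5 in wild type) and Taf7l (10.7 and 11.5). If other cells express such members, their fall is diluted. The comparison therefore cannot exclude a smaller germ cell share together with a background limit. A lower level of oocyte genes per remaining germ cell may contribute, as a hypothesis, while a different mixture of germ cell stages was not tested and some members of the maternal list are not restricted to germ cells.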
